A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

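Genomic DNA of 3 strains of Saccharomyces cerevisiae was compared by array comparative genomic hybridisation. The strains were the intraspecific hybrid R2 IVo and its parents Sc1 and Sc2. Per the labels, the DNA was cut with the restriction enzyme Hinf I, labelled with Cy3 or Cy5 by random-primed incorporation, and co-hybridised in pairs of strains. Each of the 3 samples is 1 pair of strains (hybrid against Sc1, hybrid against Sc2, and Sc1 against Sc2), and per the labels each was run on duplicate arrays with the dyes exchanged. The deposited table gives 1 log ratio per open reading frame (ORF) and sample, already combined by the authors over those arrays. The scanner, background correction, normalisation and rule for averaging are not given in the sources used here, and no intensities were used, so signal over background is unknown. The number of arrays limits the precision.

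The deposited values have no stated unit, and 3 properties were worked out from the values. The base of the logarithm was read as 2. With base 10 the largest deposited ratio would be 4.25e+05-fold, with base 2 it is 49.5-fold, and a natural logarithm (278-fold) is not excluded, so every log2 value below holds only if the base is 2. In addition, 76 cells in 57 ORFs (14, 11 and 51 in the 3 samples in the order given above) were whole numbers of at least 1000 in size, while every other cell had 3 decimals and none lay between 3 and 1000 in size. These cells were read as values that had lost their decimal point and were divided by 1000. Finally, the first-named strain was read as the numerator, which is likely from the titles and the order of the channels. The 3 samples form a triangle, so the hybrid over Sc1 plus Sc1 over Sc2 must equal the hybrid over Sc2. The departure from that sum, the closure, had an SD of 0.19 over 6123 ORFs with the directions of the titles, against 0.29, 0.33 and 0.42 when any single sample was turned. Turning all 3 samples together leaves the closure as it is, so the common direction rests on the titles alone.

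The table held 6180 entries, of which 2 were control spots. Of the 6178 ORFs, 5674 matched a locus tag of the RefSeq assembly GCF_000146045.2 (R64), which was used for gene symbols and for the order of neighbouring genes only, and 504 kept the name of the array. Chromosome and arm were read from the systematic names of 6145 ORFs. No coordinates are given because the build behind the array design is not given in the sources used here. The 55 ORFs with a missing value in any sample were left out, which leaves 6123.

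Each sample was centred on its median over ORFs (deposited medians −0.005, 0.005 and 0.013). The strain differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) from a design that treats the 3 samples as the sides of the triangle. Each ORF has 3 values and 1 residual degree of freedom. An estimate combines the direct sample with the indirect path through the third strain. P-values were adjusted by the Benjamini-Hochberg method over the 6123 ORFs, and an ORF was called at an adjusted p under 0.05. The spread behind these p-values is the array error among 3 samples of the same strains, not the spread between cultures, and an error that follows a strain's DNA through both of its samples does not enter it. The estimated prior degrees of freedom were 5.30 and the prior residual SD was 0.082 in log2.

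The fit was tested on simulated data: 50 draws of 6123 ORFs with 200 ORFs altered in Sc1. It recovered 99.8% of the ORFs raised in Sc1 by 1 in log2 for the hybrid against Sc1 and 99.9% for Sc1 against Sc2. On average 8.83% and 8.73% of the calls were false, more than the nominal 5%. With no ORF altered, the mean number of calls was 1.42 (hybrid against Sc1), 1.82 (hybrid against Sc2) and 0.94 (Sc1 against Sc2), with highest counts of 38, 52 and 23 in single draws. The prior degrees of freedom varied from 4.04 to 23.1 over the central 95% of draws, so a fit at the low end was added as an alternative.

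The position of the hybrid between its parents was computed for ORFs with a value of at least 1 in size in the Sc1 against Sc2 sample, from the other 2 samples only; 1 is the level of Sc1 and 0 the level of Sc2. Chromosome and arm medians were set against 10000 random sets of ORFs of equal number. Regions were found with a running median of 11 ORFs against 1000 shuffles of ORF order. The share of calls near chromosome ends was taken over the 10 outermost measured ORFs of each arm with Fisher's exact test (two-sided, scipy 1.17.1). Gene lists fixed in advance were summarised by calls over all ORFs, by calls adjusted over the list alone, and by the percentile of their median among 10000 random sets. A rule to add further Ty genes from their descriptions could not be applied because the gene table holds no descriptions.

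Named genes are, for each comparison, the 12 with the highest and the 12 with the lowest estimate among the called ORFs whose direct and indirect values had the same sign, up to 4 called members of each list, and the first and last ORF of each region. This rule, the tests, the lists and most alternatives were fixed before the data were examined. The alternatives were other centring and scaling, robust moderation, rules based on size, a stricter threshold, removal of multi-copy families, and other windows and selections. Removal of multi-copy families took out 123 ORFs, the members of the family lists fixed in advance and the CUP1 genes. Repeated sequences outside those lists, such as YJL114W and HXT12, stayed in that fit. Alternatives added after the data were seen were removal of the ORFs with lost decimal points, the low prior degrees of freedom, and 5 or 20 outermost ORFs. Distances from chromosome ends in kilobases, and a choice among several probes of a gene, were not run, because no coordinates were used and every ORF had 1 entry. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the other steps.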

Results

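The genome of R2 IVo, an artificial hybrid of 2 Saccharomyces cerevisiae strains, was compared with that of each parent, Sc1 and Sc2, and the parents were compared with each other. There was 1 sample per pair of strains, each a set of arrays combined by the authors, and 6123 ORFs had a value in all 3 samples. The values are hybridisation ratios. A low ratio can come from fewer copies, from sequence that differs from the array probe, or from loss of cross-hybridising copies elsewhere. A ratio near 0 can hide a difference where other copies cross-hybridise, so an ORF without a call, such as MAL12 below, is not shown to be unchanged. Ratios are in log2 with the first-named strain as numerator. Base and common direction are likely readings, and if the direction were the opposite, every strain difference below would change sign. The correlations between samples and the positions of the hybrid would stay as they are. Differences from the mean of the parents would also change in size. Across ORFs, which are not independent replicates, the hybrid over Sc1 and Sc1 over Sc2 samples had Pearson's r = −0.533 (Spearman's rho −0.081), the hybrid over Sc2 and Sc1 over Sc2 samples had r = 0.442 (rho 0.144), and the hybrid samples had r = −0.083 (rho 0.016). The estimates of MAL11, MAL13, PGU1, CSS3, YJL218W, REE1, HXT9, HXT11, HXT12, HXT15, the CUP1 genes and most Ty genes named below use at least 1 value whose decimal point was restored, while those of SEO1, SOR1, MPH2, IMA4 and RMD6 do not. The median SE of an estimate was 0.064 and each estimate rests on 3 samples.

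The largest differences between the parents were at MAL11, MAL13, the SEO1 locus, a sugar-use cluster on chromosome X and a pectinase gene. Retrotransposon and Y′ sequences also differed. MAL11, an alpha-glucoside transporter gene, and MAL13, a regulator of the MAL genes, were higher in Sc1 by 2.98 ± 0.16 (SE; limma adjusted p = 2.53e-04) and 2.81 ± 0.13 (limma adjusted p = 2.07e-04). MAL12, on the same arm, was at 0.061 ± 0.10 and was not called. SEO1, a putative permease gene on chromosome I, and its neighbour YAL066W were also higher in Sc1, by 2.90 ± 0.063 and 3.02 ± 0.20. In the opposite direction, YJL218W on chromosome X had the lowest ratio of Sc1 over Sc2, −4.90 ± 0.067 (limma adjusted p = 1.10e-06), and its neighbours HXT9, a hexose transporter gene, and REE1 were at −2.85 ± 0.077 and −3.57 ± 0.58. PGU1, which encodes endopolygalacturonase, was lower in Sc1 (−2.75 ± 0.31, limma adjusted p = 0.00743).

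In total 121 ORFs were called between the parents by limma, 32 higher in Sc1 and 89 higher in Sc2, against 586 at an unadjusted p under 0.05 where chance gives 306. The count was 61 without the ORFs with restored decimal points and 71 without the listed multi-copy families. The latter choice left in unlisted repeats such as YJL114W, so the 71 are not all outside repeated sequence. Of 21 Ty retrotransposon genes, 14 were lower in Sc1, 0 were higher and 7 were not called (16 lower when adjusted over the list alone); YMR051C was at −2.04, YJR028W at −1.77, YML045W at −1.65 and YBL005W-A at −1.60. YJL114W, a Ty4 gene outside that list, was at −2.43. Of 7 helicase genes of the subtelomeric Y′ elements, 3 were lower in Sc1 and 4 were not called (5 lower when adjusted over the list alone), with YRF1-4 at −1.04, YRF1-7 at −0.68 and YRF1-6 at −0.66. Of 13 genes of maltose and isomaltose use, 5 were higher in Sc1, 1 was lower and 7 were not called (5 higher and 3 lower when adjusted over the list alone). Besides MAL11 and MAL13 these included the permease gene MPH2 at 0.86 and, as the lower one, the isomaltase gene IMA4 at −0.72. Of 19 hexose transporter and sensor genes, 2 were higher in Sc1 (HXT15 at 1.13, HXT16 at 0.61), 2 were lower (HXT9, and HXT11 at −2.30 ± 0.32) and 15 were not called (3 higher and 3 lower when adjusted over the list alone). HXT12, which was not on the list, was at −1.79 ± 0.27. Cross-hybridisation among HXT9, HXT11 and HXT12 was not tested, so these may not be separate differences.

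CUP1-1 and CUP1-2, the tandem genes for copper metallothionein, were higher in Sc1 by 1.12 ± 0.068 each (limma adjusted p = 3.83e-04 and 3.88e-04), as was YHR054C between them at 0.99. They were the 2 called members of 7 genes of copper, sulphite and arsenic tolerance (2 when adjusted over the list alone); the sulphite pump gene SSU1 was at 0.14 ± 0.064. The sorbitol dehydrogenase gene SOR1 and the meiosis gene RMD6 were higher in Sc1 by 0.94 and 0.93, and YGL262W by 1.66. CSS3 was lower in Sc1 at −1.61 ± 0.25. Single members of other lists were called: COS12 of 11 COS family genes at 0.59 (4 higher when adjusted over the list alone, and 4 called when samples were centred on their mode), the flocculin gene FLO1 of 5 at −0.48 (1 lower when adjusted over the list alone), the vitamin B6 gene SNZ3 of 14 thiamine, pyridoxine and biotin genes at 0.52 (4 higher and 1 lower when adjusted over the list alone), and the hexokinase gene HXK1 of 24 glycolytic and fermentative genes at −0.42 (1 lower when adjusted over the list alone). REE1, PGU1, HXT11, HXT12 and CSS3 had closures of 3.09, 1.63, −1.66, 1.41 and 1.27, and none of them was called with robust moderation. The calls of FLO1, HXT16, SNZ3 and HXK1 ended at the low prior degrees of freedom.

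**Figure D1:**
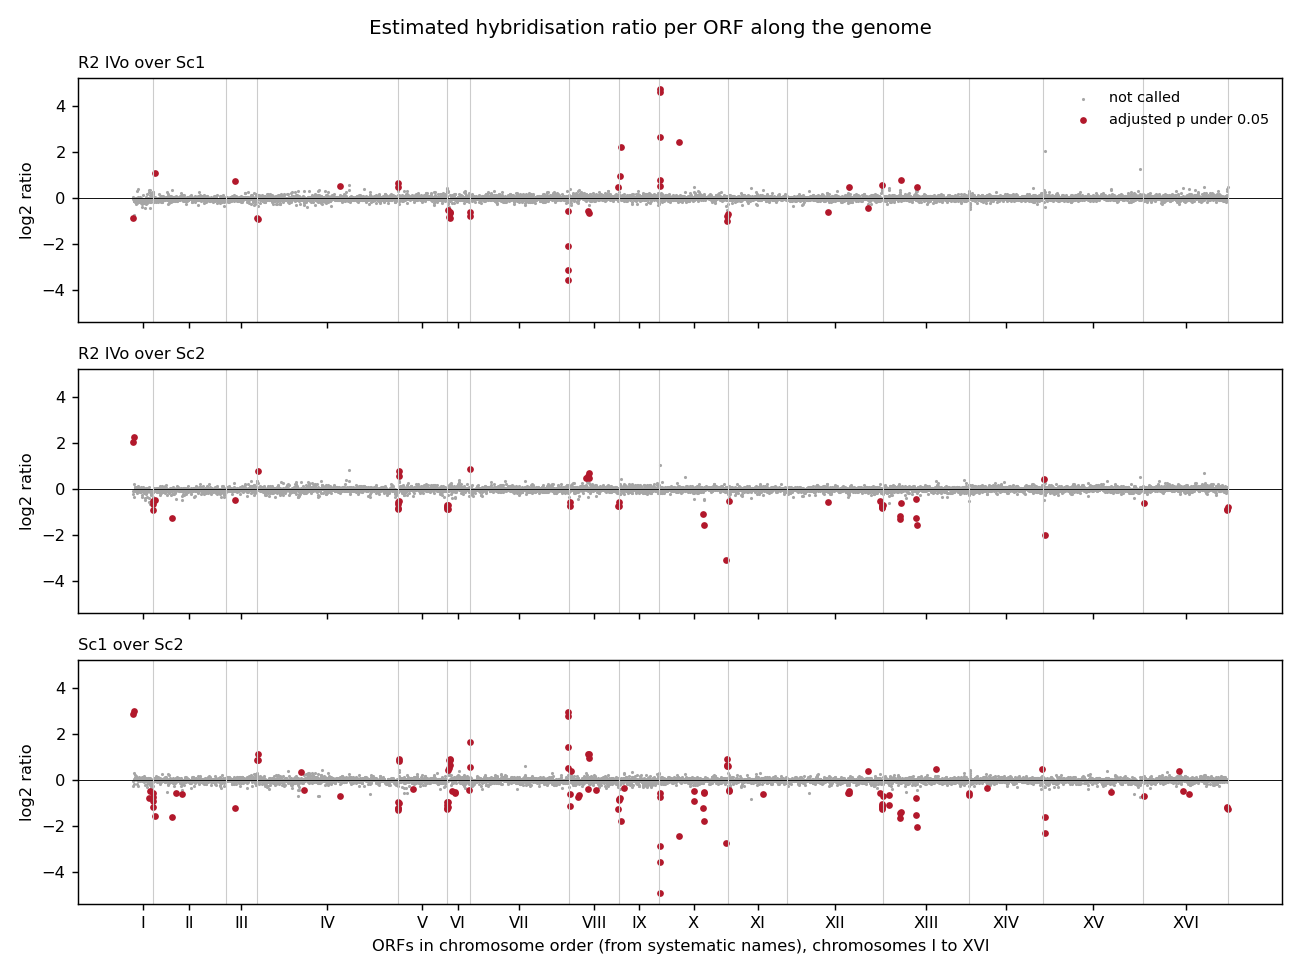
Log2 hybridisation ratio (limma estimate from 3 samples, y axis) of each ORF with a chromosome position, in chromosome order (x axis), for the hybrid over Sc1, the hybrid over Sc2 and Sc1 over Sc2; red points have an adjusted p under 0.05 and vertical lines separate chromosomes. Many called ORFs lie near chromosome ends, and the highest and lowest estimates of the upper panel are YJL218W at 4.73 on chromosome X and MAL13 at −3.54 on chromosome VII.

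Compared with Sc1, the hybrid was far lower at MAL11, MAL13 and YGR290W on the right arm of chromosome VII. It was far higher at a sugar-use cluster on the left arm of chromosome X. MAL13 was lower in the hybrid at −3.54 ± 0.13 (limma adjusted p = 1.71e-04), MAL11 at −3.13 ± 0.16 (limma adjusted p = 8.56e-04) and YGR290W, next to MAL11, at −2.10 ± 0.15 (limma adjusted p = 0.00321). MAL12, on the same arm, was at −0.074 ± 0.10 and was not called. YJL218W was higher in the hybrid by 4.73 ± 0.067 (limma adjusted p = 1.37e-06), HXT9 by 2.68 ± 0.077 and REE1, a gene linked to enolase regulation, by 4.60 ± 0.58. HXT12 and YIL171W on chromosome IX were higher by 2.24 ± 0.27 and 0.96 ± 0.090, and the Ty4 gene YJL114W by 2.44 ± 0.079. Whether the chromosome IX values reflect cross-hybridisation with the cluster on chromosome X was not tested.

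In all, 41 ORFs were called by limma between the hybrid and Sc1, 20 higher and 21 lower in the hybrid, against 489 at an unadjusted p under 0.05 where chance gives 306. The count was 15 without the ORFs with restored decimal points, 19 without the listed multi-copy families and 23 at the low prior degrees of freedom. The balance of directions depends on the centring: 12 were higher and 19 lower without it, and 36 and 26 when samples were centred on their mode. Without the ORFs with restored decimal points 1 was higher and 14 were lower, but that choice removes every ORF with a deposited value of at least 1 in size in this sample, and so the largest ratios. Of the 13 maltose and isomaltose genes, 5 were lower in the hybrid, 1 (IMA4 at 0.78) was higher and 7 were not called (5 lower and 3 higher when adjusted over the list alone); MPH2 was at −0.87 and MPH3 at −0.67. Near them on chromosomes IV and X, the sorbitol dehydrogenase genes SOR2 and SOR1 were at −0.90 and −0.98. A block on the left arm of chromosome VI was also lower, with the regulator gene ZNF1 at −0.88 and the amino acid permease gene AGP3 at −0.80. SEO1 was also lower at −0.86, YGL262W at −0.78, YJR157W at −0.79, COS12 at −0.61 (the 1 called of 11 COS genes; 3 lower when adjusted over the list alone), CUP1-2 at −0.63 and CUP1-1 at −0.54 (2 of 7 in their list, and 2 when adjusted over the list alone). Of the 21 Ty genes, 4 were higher in the hybrid, YBL101W-A at 1.09, YML039W at 0.80, YCL020W at 0.73 and YMR051C at 0.50, and 17 were not called (11 higher and 1 lower when adjusted over the list alone). The further Ty ORF YFL-TYA, outside that list, was at 1.15 and the subtelomeric YEL076C at 0.64. HXT9 was the 1 called of 19 hexose transporter and sensor genes (2 higher and 2 lower when adjusted over the list alone), and 0 of 7 Y′ helicase genes were called by limma (1 at an unadjusted p under 0.05, 0 when adjusted over the list alone). REE1 and HXT12 were not called with robust moderation, and the calls of COS12, CUP1-1, CUP1-2 and YMR051C ended at the low prior degrees of freedom.

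Compared with Sc2, the hybrid was higher at SEO1 and the copper metallothionein genes and lower at PGU1, CSS3 and Ty and Y′ sequences. SEO1 was higher by 2.04 ± 0.063 (limma adjusted p = 1.88e-04) and its neighbour YAL066W by 2.29 ± 0.20 (limma adjusted p = 0.00526). CUP1-1 and CUP1-2 were higher by 0.58 ± 0.068 and 0.49 ± 0.068, and YHR054C by 0.71 ± 0.062. PGU1 was lower in the hybrid at −3.09 ± 0.31 (limma adjusted p = 0.00947) and CSS3 at −2.00 ± 0.25 (limma adjusted p = 0.0191). The MAL11 and HXT9 loci, which set the hybrid apart from Sc1, held no called ORF against Sc2. MAL11 was at −0.15 ± 0.16, HXT9 at −0.17 ± 0.077 and YJL218W at −0.17 ± 0.067, while MAL13 was at −0.73 ± 0.13, YGR290W at −0.67 ± 0.15 and REE1 at 1.04 ± 0.58.

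In all, 56 ORFs were called by limma between the hybrid and Sc2, 11 higher and 45 lower in the hybrid, against 487 at an unadjusted p under 0.05 where chance gives 306. The count was 15 without the ORFs with restored decimal points, 36 without the listed multi-copy families and 36 at the low prior degrees of freedom. Of the 21 Ty genes, 11 were lower, 0 were higher and 10 were not called (15 lower when adjusted over the list alone). YJR028W was at −1.57, YMR051C at −1.54, YML045W at −1.31, YBL005W-A at −1.26, YMR046C at −1.25, YML040W at −1.16 and YJR026W at −1.07. Of the 7 Y′ helicase genes, 2 were lower, YRF1-4 at −0.73 and YRF1-7 at −0.60, and 5 were not called (4 lower when adjusted over the list alone). The subtelomeric ORFs YBL112C, YPR203W and YFL064C were lower, between −0.90 and −0.88. Among the higher ORFs were YGL262W at 0.88, RMD6 at 0.80, HXT15 at 0.78 (the 1 called of 19 hexose transporter and sensor genes, and 1 when adjusted over the list alone), YEL073C at 0.58, the phosphatase gene DOG2 at 0.49 and AAD15, 1 of 6 aryl-alcohol dehydrogenase genes, at 0.43 (2 higher when adjusted over the list alone). None of the 13 maltose and isomaltose genes was called by limma (2 at an unadjusted p under 0.05, 1 lower when adjusted over the list alone). When samples were centred on their mode, 1 of them was called lower in the hybrid. MAL13 had the lowest main estimate of that list, −0.73. PGU1, CSS3 and YAL066W were not called with robust moderation. The calls of CUP1-1, CUP1-2, HXT15, YEL073C, DOG2, AAD15 and YRF1-4 ended at the low prior degrees of freedom.

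**Figure D2:**
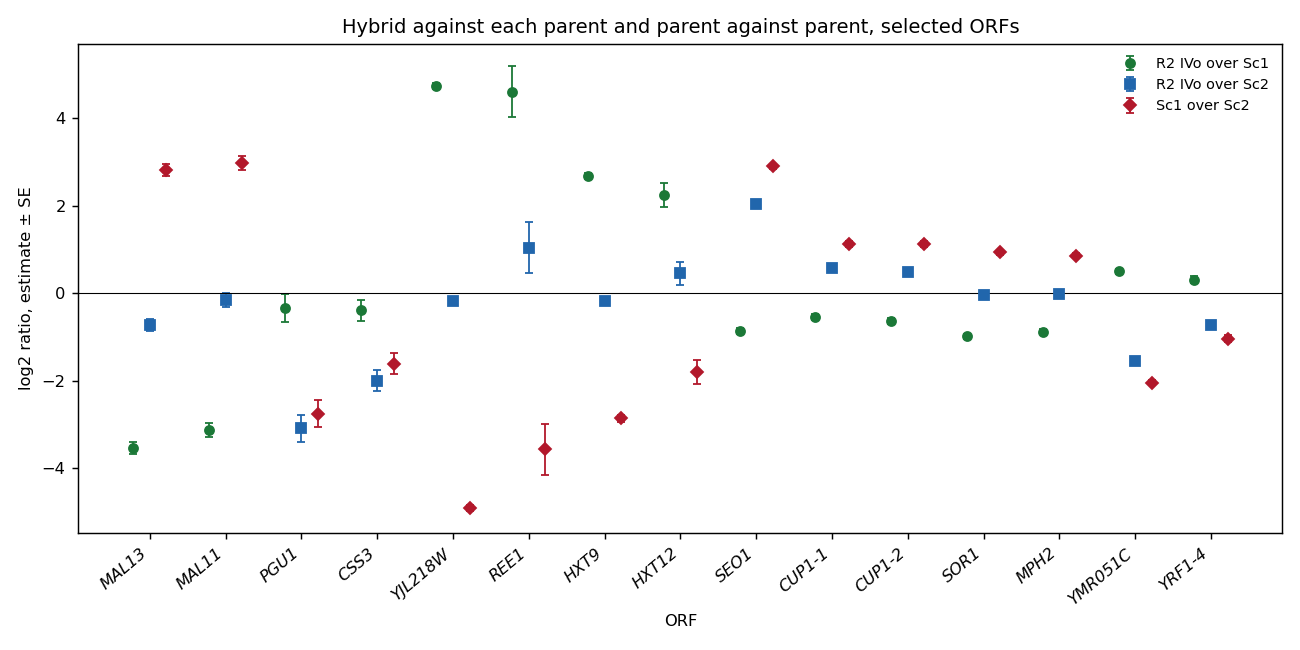
Log2 ratio (limma estimate ± SE from 3 samples, y axis) of 15 named ORFs (x axis) for the hybrid over Sc1 (green circles), the hybrid over Sc2 (blue squares) and Sc1 over Sc2 (red diamonds). At MAL11 and HXT9 the hybrid over Sc2 is near 0 (−0.15 and −0.17), at SEO1 and CUP1-1 the hybrid lies between its parents, and REE1 has the widest error bars (SE 0.58).

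The hybrid was mostly at or between the levels of its parents. Of 13 ORFs called against both parents, 12 were higher than one parent and lower than the other, among them SEO1, CUP1-1, CUP1-2, YGL262W, YML039W and YMR051C. The remaining ORF, YLR162W on chromosome XII, was lower in the hybrid than in Sc1 (−0.58 ± 0.067, limma adjusted p = 0.0197) and than in Sc2 (−0.57 ± 0.067, limma adjusted p = 0.0162); it is named although it falls outside the rule for named genes and was singled out after its values were seen. ORFs outside both parents were not counted with samples centred on their mode. With that centring 5 maltose and isomaltose genes were called below Sc1 and 1 below Sc2. At the low prior degrees of freedom 0 ORFs were outside both parents. Unchanged ORFs simulated through the same triangle gave a mean of 0.10 and at most 5 such ORFs in 100 draws, and independent lists would share 0.19. At an unadjusted p under 0.05 against both parents in the same direction there were 97 ORFs, against a simulated mean of 87.1. Across ORFs the covariance of the hybrid's estimates against the parents was 0.00212, below the 0.00356 that the shared hybrid alone gave in simulation, and the correlation was 0.0936 against 0.497. The simulation held no strain difference, and ORFs with the hybrid between its parents lower both values. The covariance and correlation therefore cannot decide whether ORFs lie outside both parents.

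For 53 ORFs the Sc1 over Sc2 sample was at least 1 in size, and the other 2 samples placed the hybrid at the level of Sc1 (within 0.25 of position 1) for 12, at that of Sc2 (within 0.25 of position 0) for 9, in between for 30 and outside the parental range for 2. The tolerance is wide: YMR051C, at 0.75, counts as at the level of Sc1, although it was called against both parents. The 2 ORFs outside, YAR040C and YKL097C, named after their values were seen, had a large value only in the Sc1 over Sc2 sample (−1.28 and −1.21, with closures of −1.34 and −1.17) and were not called, so they do not show a hybrid outside its parents. Of the 9 ORFs higher in Sc1, MAL13, MAL11 and YGR290W were at the level of Sc2 (positions −0.16, 0.032 and −0.22). The other 6 were in between, with SEO1 and YAL066W at a median of 0.71 and the CUP1 genes at a median of 0.48. Relative to the mean of the parents' levels, the median log2 difference was −0.17 for SEO1 and YAL066W and −0.20 for the CUP1 genes. Of the 44 ORFs higher in Sc2, 12 were at the level of Sc1, PGU1 among them at 0.95, and 6 were at that of Sc2, among them YJL218W (0.043), HXT9 (0.034) and YJL114W (−0.045). Another 24 of these were in between. They included Ty ORFs such as YML039W and YFL-TYA and the neighbouring ORFs YLR462W to YLR465C at the right end of chromosome XII. The 24 are therefore not separate loci. The 10 Ty genes among the 53 had a median position of 0.82. On this logarithmic scale the mean of very different parents can fall within 0.25 of the higher one, as for YJL218W. That mean would put YJL218W at −0.95 in the hybrid over Sc2 sample, where −0.22 was observed. All positions rest on 1 value per sample and carry no test.

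Genes of the cell wall and of mannoproteins, to which the title of the series points through mannoprotein release, held no called gene except the flocculin FLO1. By limma 0 of 27 cell wall mannoprotein genes were called in any of the 3 comparisons (0, 3 and 1 at an unadjusted p under 0.05 for the hybrid over Sc1, the hybrid over Sc2 and Sc1 over Sc2), and 0 when adjusted over the list alone. Their estimates ran from −0.13 to 0.25, from −0.26 to 0.51 and from −0.23 to 0.27, with PRY3 the highest in each and with an SE of 0.20. Of 26 protein mannosylation genes, 0 were called by limma (1, 2 and 1 at an unadjusted p under 0.05; 0 when adjusted over the list alone), with MNN10, a mannosyltransferase subunit gene, highest against Sc2 at 0.39 ± 0.12. Of 25 genes of glucan and chitin synthesis and remodelling, 0 were called by limma (0, 2 and 0 at an unadjusted p under 0.05; 0 when adjusted over the list alone), and all lay between −0.17 and 0.16. CWP2 was at 0.049, −0.025 and −0.073 and CCW12 at 0.0090, 0.067 and 0.058 in the same order. Among the 5 flocculin genes, FLO1 was at 0.36 ± 0.074 in the hybrid over Sc1 without a call (1 higher when adjusted over the list alone).

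Other lists held few or no calls by limma. The sodium pump genes ENA1, ENA2 and ENA5 were not called, but had medians of 0.27 for the hybrid over Sc2 and 0.30 for Sc1 over Sc2, both at percentile 99.97 of random sets (2 and 3 at an unadjusted p under 0.05, and 2 and 3 higher when adjusted over the list alone). Random sets were drawn without regard to shared sequence. If members of a family such as ENA or the seripauperins cross-hybridise, such percentiles overstate how unusual their list is. Of 4 ASP3 asparaginase genes 0 were called (1, 1 and 0 at an unadjusted p under 0.05, and as many when adjusted over the list alone). For the thiamine, pyridoxine and biotin list 0 of 14 were called against the hybrid (5 and 2 at an unadjusted p under 0.05), with 4 lower than Sc1 when adjusted over the list alone and 3 called lower than Sc1 when samples were centred on their mode (median −0.071 for the hybrid over Sc1, at percentile 0.12 of random sets). No call was made among 23 seripauperin genes (2, 4 and 1 at an unadjusted p under 0.05), although their medians of −0.066 for the hybrid over Sc2 and −0.057 for Sc1 over Sc2 were at percentiles 0.03 and 0.54 of random sets, or 9 DUP240 genes (0, 0 and 0). The same held for 18 genes of glycerol and stress (0, 1 and 2), 13 of esters and higher alcohols (2, 2 and 0) and 36 autophagy genes (0, 2 and 2). It also held for 136 genes taken as ribosomal protein genes by symbol (6, 5 and 10, or 5, 4 and 10 without RPP1, a gene for a subunit of RNase P that the symbol rule took in) and 32 proteasome genes (2, 0 and 4), and each of these 7 lists had 0 calls when adjusted over the list alone. No ORF of the mitochondrial genome or of the 2-micron plasmid was measured.

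**Figure D3:**
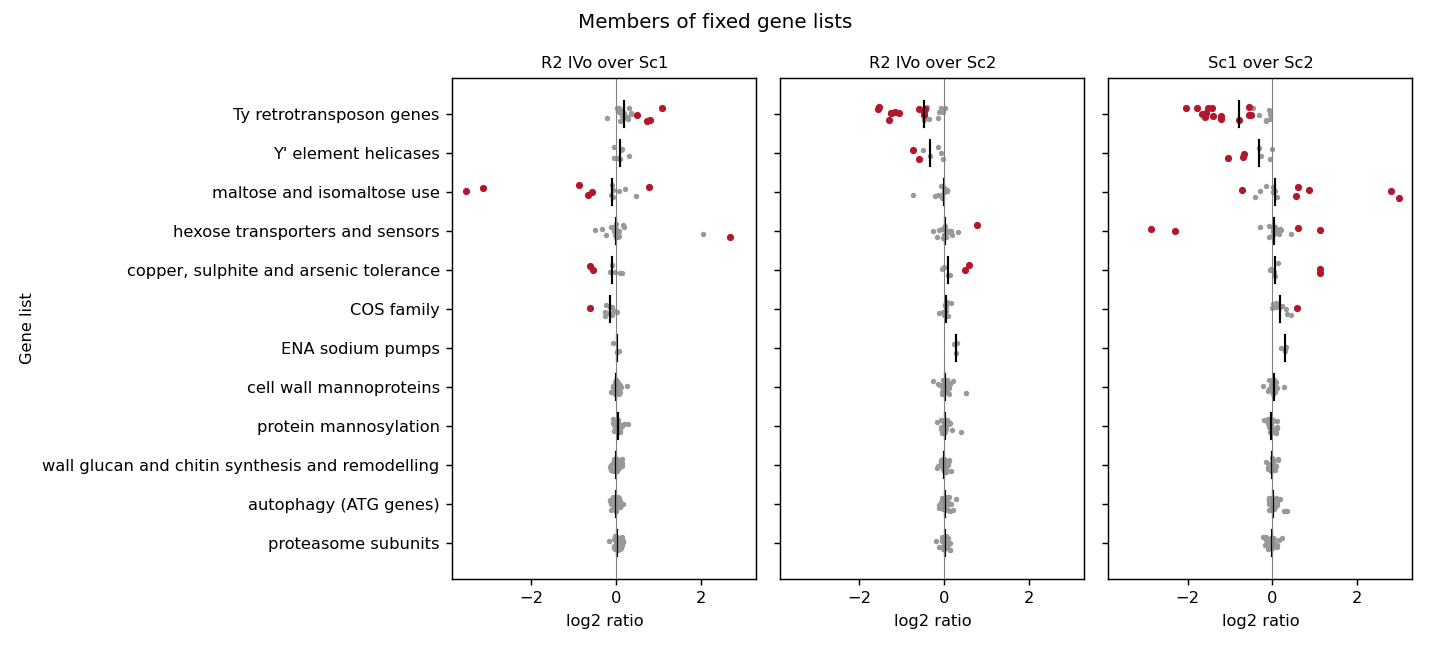
Log2 ratio (limma estimate, x axis) of the measured members of 12 gene lists (y axis) for the hybrid over Sc1, the hybrid over Sc2 and Sc1 over Sc2; each point is a gene, red points have an adjusted p under 0.05, and black bars are list medians. Ty genes have medians of 0.20, −0.47 and −0.78, while cell wall mannoproteins, with medians of 0.0047, 0.0093 and 0.039, hold no red point.

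Called ORFs were enriched near chromosome ends. Of 122 called ORFs with a position, 65 (53.3%) were among the 10 outermost of an arm, against 255 of 5968 other ORFs (4.27%; odds ratio 25.6, Fisher's exact test, two-sided, p = 2.30e-52, which treats ORFs as independent). The shares were 61.5%, 69.6% and 53.8% for the hybrid over Sc1, the hybrid over Sc2 and Sc1 over Sc2. In each comparison 4 regions of neighbouring ORFs passed the limit from shuffled order. On chromosome VI, 12 ORFs from YFL063W to ZNF1 had a median of −0.44 in the hybrid over Sc1, and 18 ORFs from COS4 to SEC53 had a median of 0.24 in Sc1 over Sc2. On chromosome X, 6 ORFs from IMA4 to IMA5 had a median of 1.73 in the hybrid over Sc1, and 9 ORFs from PGU1 to COS5 had −0.34. The right end of chromosome XII was lower in the hybrid than in Sc2 over 8 ORFs from GAB1 to YRF1-4 (median −0.71) and higher than in Sc1 over 7 ORFs from YLR460C to YRF1-4 (median 0.34). The left end of chromosome VI was lower in the hybrid than in Sc2 over 6 ORFs from YFL068W to YFL063W (median −0.73). On chromosome VIII, 8 ORFs from YHR214W to YHR219W had a median of −0.27 in Sc1 over Sc2. The remaining 4 regions held no called ORF: YDL023C to SLX5 on chromosome IV (−0.19) and HXT10 to DEG1 on chromosome VI (0.15) in the hybrid over Sc2, and YAR064W to YAR075W on chromosome I and CFD1 to EGH1 on chromosome IX (−0.18 each) in Sc1 over Sc2.

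No chromosome differed by the size of a whole copy. The lowest and highest chromosome medians were −0.10 (chromosome I) and 0.042 (chromosome VIII) in the hybrid over Sc1, −0.028 and 0.026 in the hybrid over Sc2, and −0.019 and 0.031 in Sc1 over Sc2. Small shifts outside the central 99% of random sets were found for 9, 7 and 2 of 16 chromosomes and for 13, 7 and 3 of 32 arms in these samples. No p-value was computed for these shifts.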

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

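Signals in ORFs and spots that entered no comparison were set against the Arabidopsis control spot, whose value was 0.173 in the hybrid over Sc1 sample, 0.414 in the hybrid over Sc2 sample and −0.008 in the Sc1 over Sc2 sample. The 0.414, which was above the 0.041 of the buffer control spot in the same sample, was used as the limit for all 3 samples. Smaller values, such as −0.321 for YNL337W and 0.273 for KEL3 in the hybrid over Sc1 sample, passed the control of their own sample only and are not described. The 4 ORFs below lacked a value in at least 1 sample. YPS7, which encodes a GPI-anchored aspartic protease, was at 1.05 in the hybrid over Sc2, after restoring a lost decimal point, and at −0.50 in Sc1 over Sc2. YMR052C-A was at 0.93 and PAL1, next to YPS7 on chromosome IV, at 0.42 in the hybrid over Sc2. MDJ1, a mitochondrial chaperone gene, was at 0.73 in the hybrid over Sc1. No test was possible for these values, which are otherwise as deposited and not centred.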

How the results depend on the processing

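No paired analysis was possible because the labels carry no replicate numbers and there is 1 sample per pair of strains. The alternatives with lost decimal points, low prior degrees of freedom, and 5 or 20 outermost ORFs were chosen after the data were seen. No named difference changed sign, but several alternatives could not have changed one. All called ORFs had direct and indirect values of the same sign. Recentring also moved values by far less than the smallest called estimate, 0.36 in size. For the hybrid over Sc1 (41 called), the count was 62 when centred on the mode, 19 without multi-copy families, 15 without the ORFs with lost decimal points, 23 at the low prior degrees of freedom, 23 at an adjusted p under 0.01 and 27 with a size of log2(1.5) as well; by size alone it was 65 for the indirect value at log2(1.5) and 14 for the direct sample at 1. For the hybrid over Sc2 (56 called), in the same terms, it was 36 without families, 15 without lost decimal points, 36 at the low prior degrees of freedom, 30 at 0.01, 87 for the indirect value and 13 for the direct sample at 1. For Sc1 over Sc2 (121 called), it was 71 without families, 61 without lost decimal points, 53 for the direct sample at 1 and 80 at 0.01. Without the listed families, 14, 17 and 31 of the called ORFs left the fit in these 3 comparisons, and 8, 3 and 19 stayed in it but lost their call. Without lost decimal points, 22, 37 and 51 left, and 4, 4 and 9 stayed but lost their call. The latter choice takes out many of the largest ratios by its nature. SEO1 stayed in that fit, and its main estimates were 2.04 in the hybrid over Sc2 and 2.90 in Sc1 over Sc2. The cause of the other moves was not tested, though the prior degrees of freedom were 8.38 when centred on the mode against 5.30 with the median. ORFs outside both parents fell from 1 to 0 at the low prior degrees of freedom and by size. They were not counted with samples centred on their mode, which gave more calls against Sc1. The regions rose from 12 to 28 with a window of 7 (17 with 21). Of 87 named differences, 77 stayed called with robust moderation, 72 without centring, 80 with scaling to equal spread, 87 when centred on the mode and 65 at the low prior degrees of freedom. The share near chromosome ends kept an odds ratio of 14.7 to 31.1. Signal over background is unknown, so dim ORFs could not be set apart.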

Other observations

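Beyond the named genes, which follow the rule above, the genes of this and the next paragraph were picked after their values were seen. A block on the left arm of chromosome VI that was higher in Sc1 than in Sc2 held DAK2 (dihydroxyacetone kinase) at 0.86 ± 0.061, AQY3 (an aquaglyceroporin) at 0.67 ± 0.064 and DDI3 at 0.45 ± 0.062, beside AGP3, ZNF1 and SNZ3. The hybrid was at −0.65, −0.58 and −0.51 against Sc1 for DAK2, AQY3 and DDI3, and at 0.21, 0.090 and −0.067 against Sc2, where none was called by limma. IMA1 on chromosome VII, next to MAL13, was at 0.55 in Sc1 over Sc2 and −0.56 in the hybrid over Sc1.

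Single genes outside the fixed lists were also higher in Sc2 than in Sc1 by limma. LAG1, a ceramide synthase gene, was at −0.74 ± 0.066, YAT1, a carnitine acetyltransferase gene, at −0.78 ± 0.095 (−0.904 in the Sc1 over Sc2 sample and −0.518 through the hybrid), and the glutathione peroxidase gene GPX1 at −0.58 ± 0.063. MCM5, a replicative helicase subunit gene, was at −0.54 ± 0.065, STE4, the G-protein beta subunit gene of the pheromone pathway, at −0.53 ± 0.063, and PDR12, a weak-acid pump gene, at −0.47 ± 0.068. For PDR12 the hybrid was at −0.026 against Sc2. Of 124 ORFs called in any comparison, 34 were in a fixed list and 90 in none.

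All tests in the paragraphs that follow were chosen after the results were seen. The hybrid was at least 2 below Sc1 in their direct sample at MAL13, MAL11 and YGR290W and at least 2 below Sc2 at PGU1 and CSS3, all 5 at the level of the lower parent and with restored decimal points. If base 2 holds, a mean of both parental copies cannot lie below −1; the highest value from the other 2 samples was −1.62 ± 0.26 (SE) against Sc1, which argues against both parental sets in equal parts at those 3 neighbouring ORFs, and −1.15 ± 0.42 against Sc2, which leaves this open there. Nor does it extend to all 53 ORFs with a parental difference of at least 1. Their median difference from the parental mean was −0.23 (39 below it). The 6 ORFs at the level of the higher parent were YJL218W, REE1, HXT9, YJL114W, HXT12 and HXT11, of which the HXT genes may cross-hybridise. The median difference of the 6 was 0.76. Picking ORFs at that level largely fixes the sign of this value, so it is no evidence here. These differences depend on the common direction of the ratios. An error in the direct sample alone would leave the value from the other 2 near 0, but the highest of the 5 was −1.15, and with all 3 directions reversed the pattern would move to 5 of the 6 ORFs just named, without HXT11, whose direct value of 1.49 is below 2. A candidate explanation is that the hybrid received or kept the locus from 1 parent, but sequence differences under the probes and a loss after the cross stay open and were not tested.

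Ty genes and Y′ helicase genes were lower in Sc1 than in Sc2 as groups, and near-identical copies could report the same pool of sequence. If all members of a list read 1 pool alike, they would share 1 value within their error. The SD over members was instead 9.20 times the SE for the Ty genes and 4.83 times for the Y′ helicase genes. The Ty list mixes different ORFs. YBL005W-A was at −1.60 and YBL005W-B at −0.052, YBL101W-A at −1.57 and YBL101W-B at −0.049, and YBR012W-A at −0.55 and YBR012W-B at −0.082. A mixed list can spread whether or not near-identical copies share a pool. The SDs therefore show only that a whole list did not share 1 value. They cannot decide whether smaller groups of copies report 1 pool, because each list was taken whole and the SE holds array error only. Partial cross-hybridisation between copies also stays open. No biological explanation was tested.

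Some whole chromosomes were shifted in the hybrid over Sc1 sample, although by at most −0.10. Over all 9 shifted chromosomes the indirect path, which uses the other 2 samples, showed a median share of 0.245 of the shift, and the set was split by sign after that value was seen. The lower ones, I to IV, showed a median share of only 0.178, so an array effect in that sample alone may account for most of their shift. For the higher ones the median share was 0.786. It was 0.786 for VIII, 0.92 for XV and 1.11 for XVI, but 0.165 for IX and −1.54 for VII. As a set, these chromosomes do not separate an array effect from a shift in the DNA of the hybrid or of Sc1, including its preparation.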
